A study of Mus musculus with 72 samples.

How the data were processed

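The authors deposited 1 table per library, written by RSEM, with 45706 mouse genes. The column of expected counts, the deposited estimate of reads per gene, was taken as the unit, and values were rounded, since 6.41 to 10.83 percent of them were not whole. The submitters' processing notes name STAR, RSEM and the build GRCm38, and their versions are not given in the sources used here. Symbols and positions came from GENCODE M21 for 45143 of the genes. ERCC spike-ins named in the labels had 0 entries, so no scaling by spike-in was possible. No 2 libraries held identical counts.

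Libraries were grouped by tissue, cell type and genotype as labelled, 3 in each of 24 groups. The pTreg/tTreg and Treg/Th experiments were fitted apart, as were the tissues, in 6 fits. They gave 21 comparisons and 5 tests of whether the KO effect differed between 2 cell types. Low counts were removed with filterByExpr, libraries scaled by TMM, and contrasts tested by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The standard error of a log2 fold came from its estimate and F value. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

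The comparisons, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. Bcl3 was named in each KO or OE comparison, and Foxp3, Ikzf2, Nrp1, Il10, Ctla4, Il2ra, Relb, Nfkb1 and Nfkb2 anywhere. Beyond these, up to 6 genes with the largest positive and 6 with the largest negative fold were named per comparison, if they passed, reached 5 CPM in the higher group, separated all libraries and were no predicted model or antigen receptor segment. Up to 4 members of each list with the smallest p followed, and where fewer than 3 genes passed, up to 5 with the lowest p as values. From these, genes whose call held in every alternative were preferred, a choice made after their values were seen. Gate genes, such as Foxp3 between Tregs and Th cells, were not counted as findings. Results for some genes are not reported here.

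The 24 lists came from textbook knowledge. They covered the Treg signature, effector Tregs, naive and central memory cells, the NF-kB pathway, Th1, Th2, Th17, Tfh, gut homing and residency, interferon response, cell cycle, apoptosis, immediate early and heat shock genes, glycolysis, oxidative phosphorylation, cholesterol synthesis and the mitochondrial genome. Markers of B cells, plasma cells, myeloid cells, CD8 and NK cells, erythroid, epithelial, and stromal and endothelial cells stood for other cell types. A list of the 249 protein-coding genes within 5 Mb of Bcl3 was the last, named the neighbourhood. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry.

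Alternatives were RLE size factors, no filter beyond 1 read, DESeq2 1.42.0, each library left out, only the 2 groups compared, and the replicate number as a block. After seeing the data 6 more were added. They were SI without tTreg KO libraries 2 and 3, SI without immunoglobulin genes, sex as a term, the mitochondrial share of counts as a term in the Treg/Th fits, these fits without genes changed the same way in KO and OE cells, and Th OE without genes at least 8-fold higher in WT Tregs. Equal numbers were checked as pairs by correlating residuals of libraries that share a number. Of 20 pairings, 9 had every library closest to its own number, and 3 had every correlation above 0.1. These were SI pTreg and tTreg WT (0.11 to 0.318), SI pTreg and tTreg KO (0.108 to 0.346) and spleen tTreg KO and WT (0.117 to 0.195), so blocked counts stand beside those results. The labels do not say that equal numbers mark 1 animal.

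The procedure was tested on simulated data with the dispersions of each fit and 50 changed genes per fold. In mLN Tregs it recovered 20, 48, 58 and 60 percent of genes changed 1.5, 2, 3 and 4 times, with 2.11 percent false calls. In SI pTregs recovery was 0, 2, 10 and 20 percent, where the common dispersion was 0.6962. A simulated difference between KO effects at 3-fold was recovered for 54 percent of 100 genes.

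Overlaps of calls were set against the number for independent sets. Where comparisons shared WT libraries, covariances of folds were set against 20 simulations with unchanged groups. Each comparison was refitted under all 10 splits of its 6 libraries, and each difference of KO effects under 40 drawn splits.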

Results

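The series held 72 RNA-seq libraries of mouse CD4+ T cells, 3 in each of 24 groups, sorted from mesenteric lymph nodes (mLN), spleen and small intestine (SI). In 36 of them, Foxp3+ regulatory T cells were split by a reporter into cells labelled pTreg and tTreg, from wild-type (WT) mice and from mice lacking Bcl3 (KO). The other 36 held whole Foxp3+ (Treg) and Foxp3- (Th) cells from mLN and spleen of WT mice, KO mice and mice overexpressing Bcl3 in Tregs (OE). Library totals ran from 18379492 to 69771001 estimated counts, with a median of 35968573.

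Each comparison used 3 libraries per group, and values in parentheses are log2 folds ± standard error, positive where the group named first was higher. Where one group held 3 counts or fewer, mean CPM (counts scaled to a common library total) ± SD of both groups are given in the order of the comparison, with no fold. Beside each list stand the number of its genes passing when adjusted over the list alone and the camera test of the list against all other genes. Genes that rose or fell passed an adjusted p of 0.05 in edgeR, and those named as the largest changes had all 3 libraries of one group above all 3 of the other. Totals given last in a paragraph are those that another choice, such as leaving out 1 library (without WT5), moved by more than 1.5 times. The p-values measure spread between libraries, since nothing in the labels says that libraries of 1 group came from separate animals.

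Bcl3, an atypical IkB protein that binds NF-kB dimers, was read in every group, the KO groups included. In mLN pTregs it stood at 149.8 ± 8.38 CPM in WT and 38.39 ± 1.81 in KO cells, and in mLN tTregs at 134.6 ± 4.88 and 93.32 ± 4.44. In mLN Tregs it was 147.9 ± 22.4 CPM in WT, 72.01 ± 19 in KO and 198 ± 19.8 in OE cells, and in spleen Tregs 140 ± 21.9, 85.98 ± 8.85 and 224.9 ± 4.03. The KO groups of spleen pTregs (52.97 ± 8.04 against 74.02 ± 25.1 in WT), spleen tTregs (88.83 ± 8.06 against 100.9 ± 2.06), SI pTregs (56.17 ± 7.79 against 139.3 ± 26.5) and SI tTregs (58.15 ± 25.5 against 167.3 ± 2.68) did not pass. Of these, spleen pTregs passed without WT3 (adjusted p = 0.00365) and SI tTregs without KO1 (adjusted p = 0.0345). DESeq2 called Bcl3 in SI pTregs (adjusted p = 0.0164) and SI tTregs (0.000723). In KO Th cells Bcl3 rose in spleen and did not pass in mLN (adjusted p = 0.165). They held 99.85 ± 21.2 CPM in WT and 145.1 ± 11.9 in KO cells of mLN, and 67.93 ± 17.5 and 132.7 ± 5.03 in spleen. The mean length of the Bcl3 transcripts, weighted by their abundance, was 999.42 to 1307.79 bases in the 30 KO libraries and 1588.84 to 1849.3 in the 42 others, without overlap. In mLN tTregs it was 1724.96 to 1760.42 in WT and 1264.43 to 1270.16 in KO libraries. CPM and folds were not corrected for length, and a shorter transcript gives fewer reads at an equal number of molecules. So KO folds of Bcl3 are changes in reads, not in number of transcripts. Bcl3 rose in OE Tregs of spleen (0.68 ± 0.15, adjusted p = 0.0145), a call lost without WT6 (adjusted p = 0.0786) or OE10 (adjusted p = 0.0545), and did not pass in those of mLN (0.42 ± 0.18, adjusted p = 0.404).

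**Figure D1:**
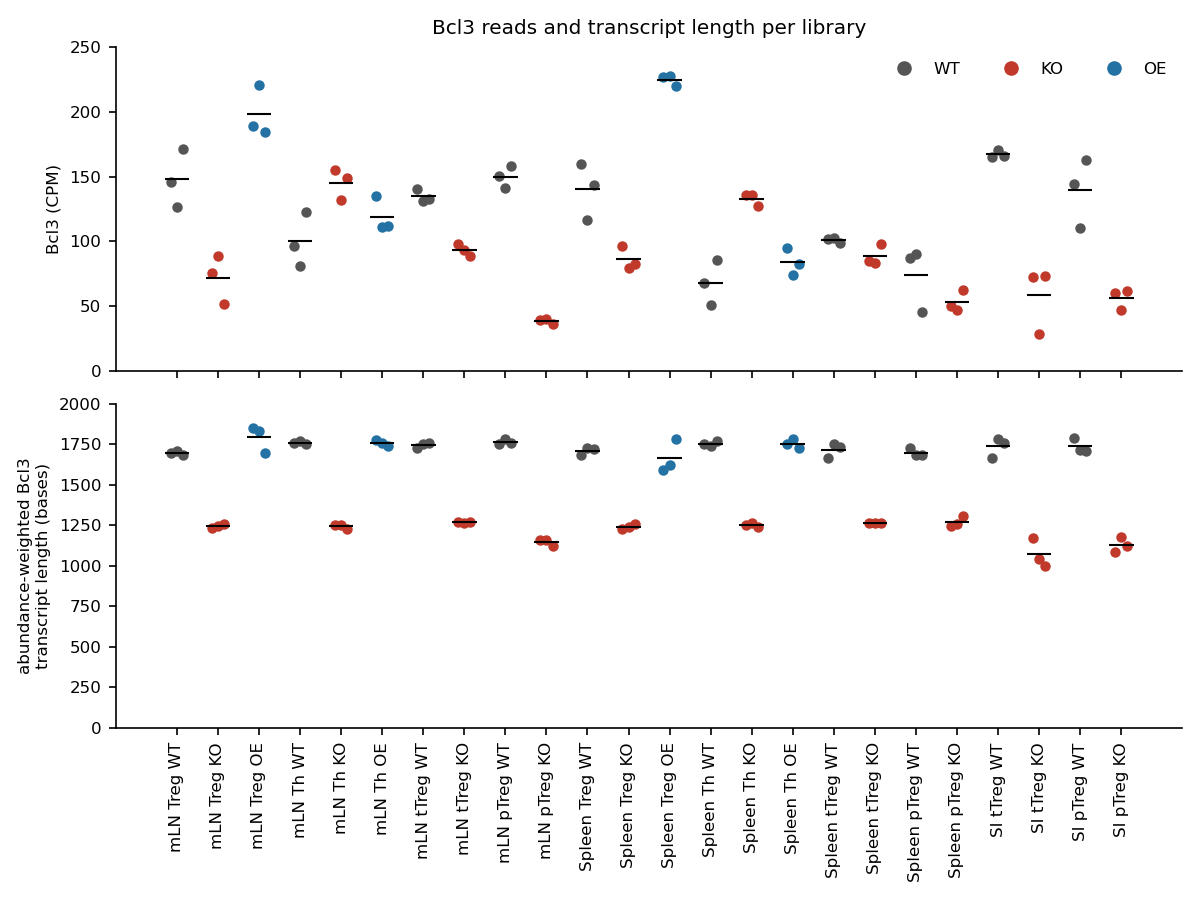
Bcl3 CPM and abundance-weighted mean length of the Bcl3 transcripts in each of 72 libraries, by group. Lines mark the mean of the 3 libraries of a group.

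In WT mLN, Tregs and Th cells differed in 2506 genes, 1438 higher and 1068 lower in Tregs. Foxp3, the gate gene, stood at 897 ± 24.1 against 2.42 ± 0.397 CPM. With it rose Il2ra (6.54 ± 0.27), Ctla4 (4.62 ± 0.20), Ikzf2 (4.77 ± 0.32) and Nrp1 (5.18 ± 0.24). Il10 (4.79 ± 0.77) was higher too, beside the NF-kB subunit genes Relb (0.62 ± 0.091) and Nfkb2 (0.65 ± 0.12). Among the largest differences, Klrg1 (17.4 ± 0.611 against 0 CPM) and Ntn4 (13.9 ± 1.74 against 0 CPM) were read in Tregs alone, and Pdlim4 (-8.16 ± 0.41), Atp8b4 (-8.09 ± 0.88) and Ggt5 (-6.95 ± 0.72) were lower. 20 of 20 Treg signature genes rose, 0 fell and 0 did not pass (20 over the list alone, camera adjusted p = 2.3e-115 for higher). With Fgl2 (5.38 ± 0.31), Tnfrsf1b (2.41 ± 0.16) and Itgae (7.12 ± 0.54), 22 of 23 effector Treg genes rose, 0 fell and 1 did not pass (22 over the list alone, camera adjusted p = 3.3e-31 for higher). With Tcf7 (-1.78 ± 0.086), Satb1 (-1.57 ± 0.10), Il7r (-1.82 ± 0.13) and Lef1 (-1.81 ± 0.13), all high in resting T cells, 8 of 14 naive and central memory genes fell, 1 rose and 5 did not pass (11 over the list alone, camera adjusted p = 2.2e-13 for lower). With Traf1 (0.99 ± 0.10), Nfkbia (0.75 ± 0.093) and Birc3 (0.70 ± 0.10), 18 of 28 NF-kB pathway genes rose, 0 fell and 10 did not pass (20 over the list alone, camera adjusted p = 3.5e-07 for higher, 0.11 with an estimated correlation). Th1 genes went both ways, Id2 (-1.71 ± 0.15) down and Gzmb (4.86 ± 0.79) up. 5 of 16 Th1 genes fell, 4 rose and 7 did not pass (11 over the list alone, camera adjusted p = 0.53). Of other cell types, 1 of 1 tested erythroid gene fell, 0 rose and 0 did not pass (1 over the list alone, camera adjusted p = 0.2) and 1 of 3 stromal and endothelial genes rose, 1 fell and 1 did not pass (2 over the list alone, camera adjusted p = 0.91). Summed markers were 1775 ± 36.6 against 719.3 ± 79.9 CPM (B cells), 54.37 ± 4.9 against 131.7 ± 7.24 (CD8 and NK cells), 26.97 ± 2.37 against 6.8 ± 3.73 (epithelial cells), 240.4 ± 33.2 against 112.5 ± 10.2 (myeloid cells) and 156.3 ± 21 against 237.9 ± 23.4 (stromal and endothelial cells).

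WT spleen gave 2589 genes, 1508 higher and 1081 lower in Tregs. Foxp3 stood at 986 ± 31.1 against 2.39 ± 0.098 CPM, and Il2ra (6.11 ± 0.14), Ctla4 (4.55 ± 0.17), Nrp1 (3.76 ± 0.19), Ikzf2 (4.74 ± 0.29) and Capg (2.90 ± 0.11) rose. So did Bcl3 (1.04, adjusted p = 9.6e-05), Relb (0.98 ± 0.11) and Nfkb2 (1.13 ± 0.11). Lrrc32 (445 ± 31.2 against 0.00525 ± 0.00909 CPM) and Sh3bgrl2 (35.8 ± 7.02 against 0 CPM) were near absent from Th cells, and Klrd1 (-7.99 ± 0.66) and Ggt5 (-7.53 ± 0.84) were lower. 20 of 20 Treg signature genes rose, 0 fell and 0 did not pass (20 over the list alone, camera adjusted p = 1.1e-155 for higher). Effector genes Tnfrsf1b (2.91 ± 0.14), Ccr8 (4.81 ± 0.26) and Icos (1.91 ± 0.15) rose. With Tcf7 (-1.69 ± 0.10) and Lef1 (-1.66 ± 0.12), 10 of 14 naive and central memory genes fell, 1 rose and 3 did not pass (11 over the list alone, camera adjusted p = 1.3e-13 for lower). With Ly6c2 (-3.75 ± 0.33) and Id2 (-2.49 ± 0.18), 9 of 16 Th1 genes fell, 2 rose and 5 did not pass (14 over the list alone, camera adjusted p = 0.002 for lower, 0.093 with an estimated correlation). The early genes Egr2 (1.70 ± 0.21) and Nr4a1 (1.39 ± 0.17) rose. 5 of 21 immediate early and heat shock genes rose, 1 fell and 15 did not pass (7 over the list alone, camera adjusted p = 0.2). With Slc16a3 (3.10 ± 0.32) and Hk2 (5.03 ± 0.72), 5 of 17 glycolysis genes rose, 1 fell and 11 did not pass (9 over the list alone, camera adjusted p = 0.00038 for higher, 0.27 with an estimated correlation). Fasl (-2.20 ± 0.13) fell. 7 of 19 apoptosis genes rose, 1 fell and 11 did not pass (8 over the list alone, camera adjusted p = 0.03 for higher, 0.082 with an estimated correlation). 6 of 9 CD8 and NK genes fell, 0 rose and 3 did not pass (7 over the list alone, camera adjusted p = 9.8e-06 for lower). Summed, other cell markers stood at 1952 ± 35.5 against 915.1 ± 126 CPM (B cells), 61.73 ± 8.29 against 164.3 ± 9.59 (CD8 and NK cells), 31 ± 3.24 against 6.5 ± 2.1 (epithelial cells), 353.7 ± 60 against 133.6 ± 20 (myeloid cells) and 215.6 ± 6.46 against 116.3 ± 20.8 (plasma cells). The total was 1374 with replicate as a block and only the 2 groups.

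Among WT Tregs of mLN, pTregs and tTregs differed in 4202 genes, 2155 higher in pTregs and 2047 lower. Il10 (6.18 ± 0.44), Ctla4 (2.35 ± 0.14) and Il2ra (0.63 ± 0.071) were higher in pTregs, Ikzf2 (-1.61 ± 0.18) and Nrp1 (-1.82 ± 0.17) lower, and Foxp3 stood at 627 ± 22.4 against 637 ± 27.6 CPM. Ccl20 (39 ± 6.78 against 0 CPM), Ccr1 (36.4 ± 8.29 against 0 CPM) and Il17re (10 ± 4.63 against 0 CPM) were read in pTregs alone, Arhgap20 (0 against 25.2 ± 2.54 CPM) and Dapk1 (0 against 14.8 ± 1.44 CPM) in tTregs alone. With Maf (3.12 ± 0.11), Icos (3.70 ± 0.14) and Ccr2 (8.74 ± 0.45), 16 of 23 effector Treg genes rose, 1 fell and 6 did not pass (17 over the list alone, camera adjusted p = 8.4e-30 for higher). S1pr1 (-2.75 ± 0.14), Klf2 (-3.49 ± 0.23) and Ccr7 (-1.92 ± 0.15) fell. 12 of 14 naive and central memory genes fell, 1 rose and 1 did not pass (13 over the list alone, camera adjusted p = 5.4e-21 for lower). With Ccr6 (3.75 ± 0.14) and Ltb4r1 (7.75 ± 0.37), 13 of 15 Th17 genes rose, 1 fell and 1 did not pass (15 over the list alone, camera adjusted p = 1.9e-43 for higher). Cxcr6 (5.80 ± 0.38) and Gpr15 (3.43 ± 0.23) rose. 10 of 14 gut homing and residency genes rose, 1 fell and 3 did not pass (11 over the list alone, camera adjusted p = 6.4e-13 for higher). With Mcm6 (0.97 ± 0.10) and Rrm2 (1.59 ± 0.24), 16 of 24 cell cycle genes rose, 0 fell and 8 did not pass (17 over the list alone, camera adjusted p = 0.00015 for higher, 0.43 with an estimated correlation). With Pkm (0.69 ± 0.083) and Hif1a (0.69 ± 0.10), 11 of 17 glycolysis genes rose, 0 fell and 6 did not pass (11 over the list alone, camera adjusted p = 0.0053 for higher, 0.36 with an estimated correlation). The Treg signature was divided, Socs2 (2.23 ± 0.11) and Capg (1.98 ± 0.10) up: 9 of 20 Treg signature genes fell, 6 rose and 5 did not pass (16 over the list alone, camera adjusted p = 0.39). Sums of markers of other cells were 2067 ± 56.9 against 1113 ± 59.9 CPM (B cells), 28.37 ± 5.49 against 44.53 ± 2.12 (CD8 and NK cells), 16.6 ± 5.88 against 30.27 ± 1.82 (epithelial cells), 368.5 ± 30.3 against 178 ± 18 (myeloid cells), 340 ± 15.4 against 180.1 ± 19.5 (plasma cells) and 72 ± 7.71 against 191.4 ± 19 (stromal and endothelial cells).

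In spleen the same split gave 3119 genes, 1479 higher and 1640 lower in pTregs. Ctla4 (0.65 ± 0.10) and Il2ra (0.59 ± 0.10) were higher and Ikzf2 (-1.79 ± 0.22) was lower. Il17re (11.1 ± 4.67 against 0 CPM) was read in pTregs alone, C2cd4d (8.10 ± 0.49), Maf (2.33 ± 0.13) and Ccr2 (5.58 ± 0.36) rose, and Col11a2 (-6.10 ± 1.17), Sostdc1 (-5.87 ± 0.77), Pdcd1 (-1.43 ± 0.15) and Bcl2 (-1.24 ± 0.11) fell. 11 of 15 Th17 genes rose, 2 fell and 2 did not pass (14 over the list alone, camera adjusted p = 4.9e-24 for higher). With Itgb7 (0.86 ± 0.067), Gpr183 (1.67 ± 0.15) and Gpr15 (3.12 ± 0.29), 9 of 14 gut homing and residency genes rose, 1 fell and 4 did not pass (10 over the list alone, camera adjusted p = 8.6e-11 for higher). Nfkbiz (-2.49 ± 0.22), Tnf (-1.96 ± 0.25) and Ikbke (-1.15 ± 0.16) fell. 14 of 28 NF-kB pathway genes fell, 2 rose and 12 did not pass (20 over the list alone, camera adjusted p = 5.7e-05 for lower, 0.17 with an estimated correlation). With mt-Co2 (0.56 ± 0.11), 9 of 13 mitochondrial genome genes rose, 0 fell and 4 did not pass (9 over the list alone, camera adjusted p = 5.7e-05 for higher, 0.25 with an estimated correlation), and with Uqcrc2 (0.40 ± 0.090) from the nucleus, 7 of 21 oxidative phosphorylation genes rose, 0 fell and 14 did not pass (11 over the list alone, camera adjusted p = 0.00016 for higher, 0.3 with an estimated correlation). 6 of 18 cholesterol synthesis genes rose, 0 fell and 12 did not pass (6 over the list alone, camera adjusted p = 0.0014 for higher, 0.17 with an estimated correlation), Msmo1 (0.74 ± 0.10) among them. Markers of other cells stood, summed, at 9.033 ± 2.3 against 30.17 ± 3.65 CPM (epithelial cells). The total was 1744 without tTreg WT1 and 1918 without tTreg WT2.

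SI pTregs and tTregs of WT mice differed in 49 genes, 29 higher and 20 lower in pTregs. Ccl20 (65.1 ± 46.4 against 0 CPM), Il17re (35.8 ± 8.27 against 0 CPM), Rbm24 (113 ± 20.3 against 0 CPM) and Ppp1r14c (32.4 ± 8.27 against 0 CPM) were read in pTregs alone, and Cd160 (-3.22 ± 0.35) was lower. 5 of 18 Th17 genes rose, 0 fell and 13 did not pass (14 over the list alone, camera adjusted p = 1.3e-33 for higher), and 3 of 10 Th2 genes fell, 0 rose and 7 did not pass (8 over the list alone, camera adjusted p = 1.5e-19 for lower). Other cell types had summed markers of 116.4 ± 76.2 against 679.1 ± 76.9 CPM (CD8 and NK cells), 43.8 ± 18.9 against 113.1 ± 20.5 (epithelial cells) and 1.9 ± 1.28 against 26.7 ± 8.31 (erythroid cells). The total was 15 without pTreg WT1, 18 without tTreg WT1, 14 without pTreg WT2, 15 without tTreg WT2, 23 without pTreg WT3, 22 without tTreg WT3, 226 with DESeq2, 160 fitting only the 2 groups compared, 117 with replicate as a block and only the 2 groups and 172 without tTreg KO libraries 2 and 3.

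**Figure D2:**
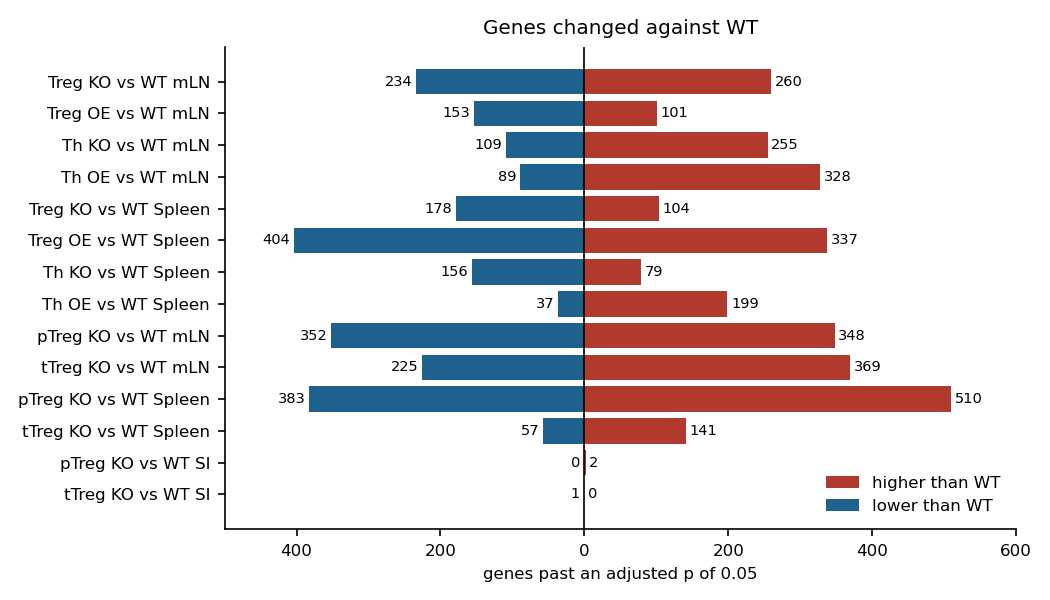
Genes higher (right) and lower (left) than WT at adjusted p under 0.05 in each of 14 comparisons of KO or OE with WT cells, 3 libraries per group.

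KO and WT Tregs of mLN differed in 494 genes, 260 higher and 234 lower in KO cells. Bcl3 (-1.04 ± 0.18) fell, while Foxp3 (597 ± 154 against 897 ± 24.1 CPM, adjusted p = 0.106, 0.0381 with DESeq2) did not pass. Lad1 (7.99 ± 0.60), C2cd4d (6.36 ± 0.58), Lingo4 (6.09 ± 1.07), Apol11b (5.99 ± 1.13), Wnt10a (5.52 ± 0.98) and Sytl4 (5.04 ± 0.80) rose most. Lad1 went the other way in KO tTregs of the other experiment without passing (10.31 ± 2.89 against 48.99 ± 4.25 CPM in mLN, 9.38 ± 0.511 against 42.26 ± 3.03 in spleen, adjusted p = 0.105 and 0.375). C2cd4d and Lingo4 were pTreg genes there (mLN means 34.9 and 50.89 CPM in WT, 51.21 and 53.8 in KO, at most 0.2333 in tTregs). The share of pTregs here was not tested. Ctse (-4.67 ± 0.29), which encodes cathepsin E, fell, and Capn11 (0 against 6.09 ± 3.24 CPM) and Cxcr2 (0 against 6.03 ± 1.34 CPM) were read in WT cells alone. With Fgl2 (2.16 ± 0.25), Batf (0.82 ± 0.12), Cxcr3 (1.41 ± 0.22) and Cd44 (1.17 ± 0.18), 7 of 23 effector Treg genes rose, 1 fell and 15 did not pass (15 over the list alone, camera adjusted p = 1.3e-11 for higher). Ccl5 (2.49 ± 0.33) and Id2 (1.20 ± 0.15) rose and Eomes (-2.79 ± 0.45) fell. 5 of 16 Th1 genes rose, 1 fell and 10 did not pass (12 over the list alone, camera adjusted p = 8.1e-09 for higher). With Cxcr6 (3.64 ± 0.28), 8 of 17 Th17 genes rose, 0 fell and 9 did not pass (9 over the list alone, camera adjusted p = 3.6e-13 for higher). Icos (1.11 ± 0.20) and Sh2d1a (0.82 ± 0.14) rose. With Satb1 (-0.76 ± 0.10), 5 of 14 naive and central memory genes fell, 0 rose and 9 did not pass (7 over the list alone, camera adjusted p = 3.7e-06 for lower). With Stmn1 (-1.07 ± 0.20), 5 of 24 cell cycle genes fell, 0 rose and 19 did not pass (9 over the list alone, camera adjusted p = 3.1e-07 for lower, 0.097 with an estimated correlation), and 3 of 23 interferon response genes fell, 0 rose and 20 did not pass (9 over the list alone, camera adjusted p = 0.00038 for lower, 0.59 with an estimated correlation). Bcl2l1 (1.21 ± 0.15) rose and Nfkbid (-1.25 ± 0.16) fell. Within 5 Mb of Bcl3, Slc1a5 (-0.93 ± 0.091), Ccdc61 (-2.30 ± 0.20) and Kcnn4 (-0.76 ± 0.079) fell. 9 of 84 neighbourhood genes fell, 4 rose and 71 did not pass (23 over the list alone, camera adjusted p = 0.013 for lower, 0.13 with an estimated correlation, the mean fold having the other sign). 3 of 8 CD8 and NK genes fell, 0 rose and 5 did not pass (3 over the list alone, camera adjusted p = 0.00038 for lower), and 0 of 11 myeloid genes rose, 0 fell and 11 did not pass (5 over the list alone, camera adjusted p = 0.013 for higher, 0.43 with an estimated correlation). Other cell markers summed to 17.5 ± 11.7 against 54.37 ± 4.9 CPM (CD8 and NK cells), 47.07 ± 5.2 against 26.97 ± 2.37 (epithelial cells) and 458.6 ± 46.1 against 240.4 ± 33.2 (myeloid cells). The total was 273 without WT5, 290 without WT7, 292 without KO3 and 877 with DESeq2. WT libraries and KO1 were male, KO2 and KO3 female, here and in the next KO comparisons of this experiment. KO is thus partly mixed with sex. A term for sex rests on KO1, and totals with it are not given.

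In spleen, KO Tregs differed in 282 genes, 104 higher and 178 lower. Irgc1 (5.70 ± 0.70) and Wnt10a (4.06 ± 0.47) rose, and Lad1 (16.1 ± 2.42 against 0 CPM) was read in KO cells alone. Ctse (-4.59 ± 0.21), Zfp526 (-4.53 ± 0.33), Ptprv (-3.96 ± 0.71), Bcam (-3.92 ± 0.55) and Cd22 (-3.81 ± 0.55) fell most. Foxp3 fell (-0.52 ± 0.12, adjusted p = 0.0245). Any 1 library left out ended the call, with adjusted p from 0.0582 (KO1) to 0.0958 (KO3). Foxp3 kept folds from -0.504 to -0.548, and -0.521 with sex as a term. It did not pass in KO spleen tTregs (670.9 ± 68.5 against 650.1 ± 12 CPM) or pTregs (677.2 ± 19.1 against 645.8 ± 48.6) of the other experiment. Bcl3 fell too (-0.70 ± 0.15, and -0.608 with sex as a term). Leaving out WT5, WT7, KO2 or KO3 ended that call (adjusted p from 0.0881 to 0.126). Stmn1 (-1.13 ± 0.16), Birc5 (-2.13 ± 0.31) and Rrm2 (-1.35 ± 0.21) fell. 9 of 24 cell cycle genes fell, 0 rose and 15 did not pass (14 over the list alone, camera adjusted p = 6.4e-20 for lower). 3 of 23 effector Treg genes fell, 0 rose and 20 did not pass (8 over the list alone, camera adjusted p = 0.0011 for lower, 0.23 with an estimated correlation). Fasl (1.27 ± 0.13) and Bcl2l1 (0.92 ± 0.13) rose, and Gpr83 (-1.44 ± 0.18), Myb (-1.27 ± 0.20) and Pglyrp1 (-1.36 ± 0.17) fell. By the Bcl3 locus, Igsf23 (2.09 ± 0.20) rose and Slc1a5 (-1.28 ± 0.13) and Ccdc61 (-1.98 ± 0.22) fell. 11 of 85 neighbourhood genes fell, 6 rose and 68 did not pass (30 over the list alone, camera adjusted p = 0.021 for lower, 0.19 with an estimated correlation). Of markers of other cells, sums were 21.8 ± 9.32 against 61.73 ± 8.29 CPM (CD8 and NK cells). The total was 180 without WT5, 167 without WT7, 161 without KO2, 165 without KO3, 556 with DESeq2 and 143 without genes changed the same way in KO and OE.

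OE and WT Tregs of mLN differed in 254 genes, 101 higher and 153 lower in OE cells. Foxp3 (-1.39 ± 0.19) fell. Lad1 (11.15 ± 0.60), Ifi208 (2.51 ± 0.32), Sema4a (2.03 ± 0.34), Rell1 (1.99 ± 0.28) and Myo6 (1.93 ± 0.29) rose most. Camk2b (-4.32 ± 0.31) and Ctse (-3.91 ± 0.28) fell, and Capn11 (0 against 6.09 ± 3.24 CPM) and Cxcr2 (0.0071 ± 0.0123 against 6.03 ± 1.34 CPM) were near absent from OE cells. 3 of 20 Treg signature genes fell, 0 rose and 17 did not pass (6 over the list alone, camera adjusted p = 5.4e-05 for lower, 0.28 with an estimated correlation). With Cd44 (-1.32 ± 0.19), Tnfrsf1b (-0.89 ± 0.15) and Batf (-0.72 ± 0.12), 3 of 23 effector Treg genes fell, 0 rose and 20 did not pass (6 over the list alone, camera adjusted p = 1.9e-06 for lower, 0.29 with an estimated correlation). With Tcf7 (0.49 ± 0.084), 3 of 14 naive and central memory genes rose, 0 fell and 11 did not pass (7 over the list alone, camera adjusted p = 0.00065 for higher, 0.28 with an estimated correlation). Ccna2 (-2.52 ± 0.39) and Rrm2 (-1.28 ± 0.23) fell. 4 of 24 cell cycle genes fell, 0 rose and 20 did not pass (8 over the list alone, camera adjusted p = 1.9e-06 for lower, 0.28 with an estimated correlation). Id2 (1.42 ± 0.15) and Il18r1 (1.68 ± 0.29) rose, and Il9r (-1.68 ± 0.31), Lta (-0.83 ± 0.14), Cxcr5 (-1.26 ± 0.20) and Bcl2l1 (-1.85 ± 0.16) fell. The B cell gene Ighm (-0.90 ± 0.11) was lower too. Other cell markers summed to 968.2 ± 138 against 1775 ± 36.6 CPM (B cells) and 17.27 ± 1 against 26.97 ± 2.37 (epithelial cells). The total was 165 without WT6, 153 without WT7, 163 without OE10, 488 with DESeq2, 393 fitting only the 2 groups compared and 157 without genes changed the same way in KO and OE.

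In spleen, OE Tregs differed in 741 genes, 337 higher and 404 lower. Foxp3 (-1.44 ± 0.12) and Ctla4 (-0.98 ± 0.15) fell. Ifi208 (2.67 ± 0.24), Myo6 (2.47 ± 0.21), Igfbp4 (2.40 ± 0.20) and Sema4a (2.17 ± 0.35) rose most, and Lad1 (63.8 ± 5.07 against 0 CPM) was read in OE cells alone. Ptprv (-7.96 ± 0.92), Adam8 (-5.04 ± 0.61), Camk2b (-3.80 ± 0.21) and Ctse (-3.73 ± 0.20) fell most. With Entpd1 (-1.15 ± 0.15) and Tnfrsf18 (-0.56 ± 0.11), 8 of 20 Treg signature genes fell, 0 rose and 12 did not pass (9 over the list alone, camera adjusted p = 3.7e-08 for lower). With Batf (-1.25 ± 0.12), Tnfrsf1b (-0.91 ± 0.13), Icos (-0.94 ± 0.15) and Cd44 (-1.11 ± 0.22), 8 of 23 effector Treg genes fell, 0 rose and 15 did not pass (15 over the list alone, camera adjusted p = 1.3e-11 for lower). S1pr1 (0.84 ± 0.10), Bcl2 (0.93 ± 0.15) and Tcf7 (0.56 ± 0.10) rose. 8 of 14 naive and central memory genes rose, 0 fell and 6 did not pass (9 over the list alone, camera adjusted p = 3.6e-10 for higher). Rrm2 (-1.99 ± 0.21), Birc5 (-2.49 ± 0.32), Top2a (-1.93 ± 0.29) and Plk1 (-2.69 ± 0.45) fell. 13 of 24 cell cycle genes fell, 0 rose and 11 did not pass (17 over the list alone, camera adjusted p = 7.7e-15 for lower). 4 of 28 NF-kB pathway genes fell, 0 rose and 24 did not pass (6 over the list alone, camera adjusted p = 0.00028 for lower, 0.2 with an estimated correlation). Bcl2l1 (-2.13 ± 0.13), Il12rb1 (-1.20 ± 0.15), Ccr4 (-1.76 ± 0.31) and Cxcr5 (-1.53 ± 0.27) fell. 1 of 12 B cell genes fell, 0 rose and 11 did not pass (1 over the list alone, camera adjusted p = 0.0043 for lower, 0.21 with an estimated correlation). Summed markers stood at 969.1 ± 17.4 against 1952 ± 35.5 CPM (B cells), 18.63 ± 1.67 against 31 ± 3.24 (epithelial cells) and 105.7 ± 10.5 against 177.2 ± 15.9 (stromal and endothelial cells). Erythroid ones ran from 6.9 to 722.1 CPM among the OE libraries. The total was 449 without WT5, 483 without WT6, 447 without WT7, 398 without OE10, 417 without OE11 and 1118 with DESeq2.

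KO and WT Th cells of mLN differed in 364 genes, 255 higher and 109 lower in KO cells. Ccl4 (4.74 ± 0.65) and Ctla4 (1.71 ± 0.18) rose, and Bcl3 did not pass (0.54 ± 0.18). Klrg1 (4.81 ± 3.44 against 0 CPM) and Havcr2 (1.38 ± 0.565 against 0 CPM) were read in KO cells alone, Cxcr2 (0.0235 ± 0.0407 against 15.3 ± 3.72 CPM) was near absent from them, and Ctse (-5.24 ± 0.30) and Zfp526 (-4.18 ± 0.49) fell. With Entpd1 (3.56 ± 0.33), 7 of 20 Treg signature genes rose, 0 fell and 13 did not pass (15 over the list alone, camera adjusted p = 3.2e-15 for higher). With Batf (1.07 ± 0.13) and Pdcd1 (1.37 ± 0.19), 15 of 23 effector Treg genes rose, 0 fell and 8 did not pass (18 over the list alone, camera adjusted p = 3.6e-33 for higher). Ccl5 (3.62 ± 0.34) and Nkg7 (3.02 ± 0.33) rose. 6 of 16 Th1 genes rose, 0 fell and 10 did not pass (7 over the list alone, camera adjusted p = 9.9e-11 for higher). With Maf (1.28 ± 0.20), 8 of 17 Th17 genes rose, 0 fell and 9 did not pass (10 over the list alone, camera adjusted p = 7e-21 for higher). Cxcr5 (1.59 ± 0.20), Tox2 (1.98 ± 0.31) and Icos (1.17 ± 0.20) rose. 5 of 12 Tfh genes rose, 0 fell and 7 did not pass (7 over the list alone, camera adjusted p = 9.5e-10 for higher). With Rrm2 (1.55 ± 0.23) and Birc5 (1.51 ± 0.26), 9 of 24 cell cycle genes rose, 0 fell and 15 did not pass (12 over the list alone, camera adjusted p = 5.5e-11 for higher). 5 of 23 interferon response genes fell, 0 rose and 18 did not pass (16 over the list alone, camera adjusted p = 6e-06 for lower, 0.37 with an estimated correlation). Bcl2l1 (1.00 ± 0.15) rose, and Il7r (-0.87 ± 0.12) and Bbc3 (-1.57 ± 0.23) fell. By the Bcl3 locus, Igsf23 (1.72 ± 0.19) rose and Slc1a5 (-1.44 ± 0.092) and Kcnn4 (-0.62 ± 0.079) fell. Of other cell types, summed markers stood at 85.4 ± 7.3 against 131.7 ± 7.24 CPM (CD8 and NK cells). The total was 709 with DESeq2, 211 fitting only the 2 groups compared and 143 without genes changed the same way in KO and OE.

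In spleen, KO Th cells differed in 235 genes, 79 higher and 156 lower. Bcl3 (0.97 ± 0.16) itself rose, beside Cd86 (2.53 ± 0.23) and Igsf23 (2.28 ± 0.20). Ctse (-4.76 ± 0.21), Zfp526 (-3.60 ± 0.32), Plac8 (-3.39 ± 0.59) and Pglyrp1 (-2.66 ± 0.18) fell most, and Cxcr2 (0.0182 ± 0.0158 against 13.2 ± 2.27 CPM) was near absent from KO cells. With Id2 (-1.52 ± 0.18) and Il18rap (-2.38 ± 0.40), 5 of 16 Th1 genes fell, 0 rose and 11 did not pass (7 over the list alone, camera adjusted p = 1.4e-11 for lower). With Cxcr6 (-2.36 ± 0.35) and Ccr9 (-1.31 ± 0.22), 4 of 14 gut homing and residency genes fell, 0 rose and 10 did not pass (7 over the list alone, camera adjusted p = 9.3e-11 for lower). Bbc3 (-1.70 ± 0.20) fell and Bcl2l1 (0.71 ± 0.13) rose. 1 of 19 apoptosis genes rose, 1 fell and 17 did not pass (4 over the list alone, camera adjusted p = 0.006 for lower). With Klrb1c (-2.65 ± 0.42), 1 of 9 CD8 and NK genes fell, 0 rose and 8 did not pass (2 over the list alone, camera adjusted p = 0.00074 for lower). Il2rb (-1.34 ± 0.19), Nt5e (-0.80 ± 0.13), Slamf6 (-0.66 ± 0.10), Il7r (-0.87 ± 0.13), Slc1a5 (-1.49 ± 0.13) and Ccdc61 (-2.19 ± 0.22) fell. Summed, these markers stood at 92.93 ± 14.1 against 164.3 ± 9.59 CPM (CD8 and NK cells). The total was 472 with DESeq2, 136 fitting only the 2 groups compared and 150 without genes changed the same way in KO and OE.

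Th cells of OE and WT mice differed in 417 genes in mLN, 328 higher and 89 lower in OE mice. Genes of Tregs rose, among them Foxp3 (3.60 ± 0.22), Il2ra (2.84 ± 0.24), Ctla4 (2.01 ± 0.18), Nrp1 (2.20 ± 0.22) and Ikzf2 (2.58 ± 0.30). Axl (4.20 ± 0.38) and Itgae (4.19 ± 0.49) rose too, and Lad1 (15.4 ± 2 against 0 CPM) and Klrg1 (4.01 ± 0.482 against 0 CPM) were read in OE cells alone. Ctse (-4.70 ± 0.29) and Camk2b (-2.97 ± 0.29) fell, and Cxcr2 (0.0237 ± 0.0227 against 15.3 ± 3.72 CPM) was near absent from OE cells. 19 of 20 Treg signature genes rose, 0 fell and 1 did not pass (19 over the list alone, camera adjusted p = 2.7e-79 for higher). With Fgl2 (2.46 ± 0.30) and Pdcd1 (1.51 ± 0.19), 13 of 23 effector Treg genes rose, 0 fell and 10 did not pass (20 over the list alone, camera adjusted p = 2.9e-36 for higher). With Maf (1.38 ± 0.20) and Ahr (1.38 ± 0.26), 8 of 17 Th17 genes rose, 0 fell and 9 did not pass (10 over the list alone, camera adjusted p = 3.3e-13 for higher). 6 of 12 Tfh genes rose, 0 fell and 6 did not pass (8 over the list alone, camera adjusted p = 6e-12 for higher). With Rrm2 (1.32 ± 0.23), 6 of 24 cell cycle genes rose, 0 fell and 18 did not pass (13 over the list alone, camera adjusted p = 6.4e-11 for higher). Of other cell types, the B cell gene Cd79b (2.83 ± 0.26) and Cd74 (2.23 ± 0.34), of antigen-presenting cells, rose: 1 of 10 B cell genes rose, 0 fell and 9 did not pass (2 over the list alone, camera adjusted p = 9e-05 for higher) and 1 of 11 myeloid genes rose, 0 fell and 10 did not pass (1 over the list alone, camera adjusted p = 0.015 for higher, 0.38 with an estimated correlation). Bcl3 did not pass (0.25). The summed markers stood at 200.9 ± 60.8 against 112.5 ± 10.2 CPM (myeloid cells). The total was 255 without OE11, 727 with DESeq2, 121 fitting only the 2 groups compared, 154 without genes changed the same way in KO and OE and 247 without genes 8-fold higher in WT Tregs.

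In spleen, Th cells of OE mice differed in 236 genes, 199 higher and 37 lower. Foxp3 (3.59 ± 0.14), Il2ra (2.25 ± 0.12), Nrp1 (2.04 ± 0.18), Ikzf2 (2.29 ± 0.27) and Ctla4 (1.55 ± 0.15) rose. Lrrc32 (27.2 ± 6.36 against 0.00525 ± 0.00909 CPM), Lad1 (8.92 ± 1.85 against 0 CPM) and Sh3bgrl2 (5.21 ± 0.866 against 0 CPM) were near absent from WT Th cells, and Dnah7a (6.50 ± 0.53) and Il1r2 (4.97 ± 0.56) rose. Ctse (-4.52 ± 0.21) and Camk2b (-3.88 ± 0.21) fell, and Cxcr2 (0.0155 ± 0.0135 against 13.2 ± 2.27 CPM) was near absent from OE cells. 15 of 20 Treg signature genes rose, 0 fell and 5 did not pass (18 over the list alone, camera adjusted p = 3.4e-104 for higher). With Itgae (3.44 ± 0.40), Ccr8 (1.93 ± 0.23), Pdcd1 (1.66 ± 0.22) and Tnfrsf1b (0.90 ± 0.13), 11 of 23 effector Treg genes rose, 0 fell and 12 did not pass (14 over the list alone, camera adjusted p = 1.7e-24 for higher). 4 of 10 Th2 genes rose, 0 fell and 6 did not pass (4 over the list alone, camera adjusted p = 1.9e-06 for higher), and 4 of 12 Tfh genes rose, 0 fell and 8 did not pass (6 over the list alone, camera adjusted p = 6.1e-09 for higher). With Rrm2 (1.25 ± 0.21), 1 of 24 cell cycle genes rose, 0 fell and 23 did not pass (5 over the list alone, camera adjusted p = 9.1e-07 for higher). Ccr9 (-1.25 ± 0.22) fell. Bcl3 did not pass (0.30). The total was 411 with DESeq2, 134 fitting only the 2 groups compared and 125 without genes 8-fold higher in WT Tregs.

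**Figure D3:**
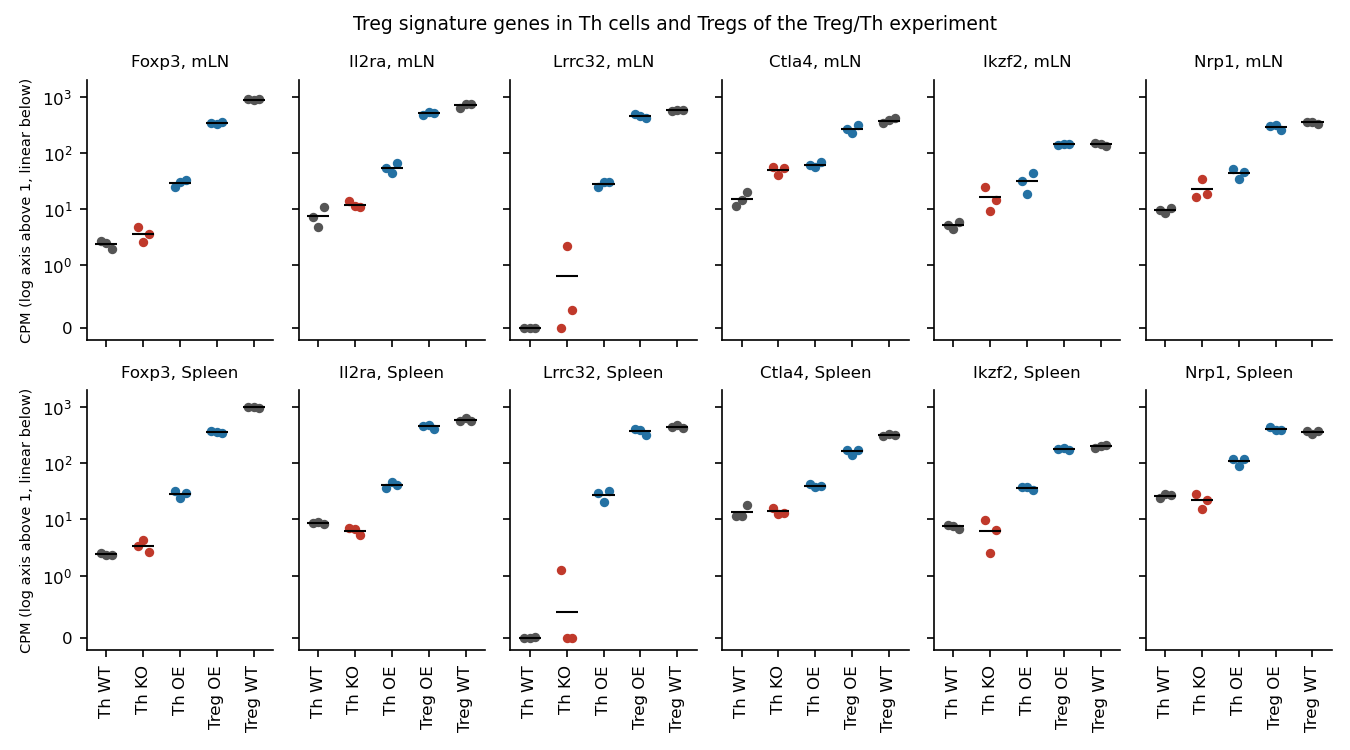
CPM of 6 Treg genes in Th cells of WT, KO and OE mice and in Tregs of OE and WT mice, in mLN and spleen. Points are libraries, 3 per group.

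The KO effect differed between mLN Tregs and Th cells in 59 genes, 19 more positive in Tregs and 40 more negative. Bcl3 changed by -1.04 ± 0.18 against 0.54 ± 0.18 in Th cells (difference -1.58 ± 0.26, adjusted p = 0.00867). The chemokine gene Ccl4 changed by -1.31 ± 0.58 against 4.74 ± 0.65 (-6.05 ± 0.86, adjusted p = 0.00276) and Ctla4, which did not pass without Treg WT7 (adjusted p = 0.0601), by 0.35 ± 0.17 against 1.71 ± 0.18 (-1.37 ± 0.25, adjusted p = 0.0162). The total was 29 without Treg WT7, 196 with DESeq2 and 2 with replicate as a block. With replicate as a block, the differences hardly moved but did not pass, at -1.62 for Bcl3 (adjusted p = 0.123), -5.954 for Ccl4 (0.17) and -1.387 for Ctla4 (0.116). In spleen 39 genes differed, 22 more positive and 17 more negative in Tregs. Bcl3 changed by -0.70 ± 0.15 against 0.97 ± 0.16 (-1.67 ± 0.22, adjusted p = 0.00159). That total was 128 with DESeq2 and 7 with replicate as a block.

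KO and WT pTregs of mLN differed in 700 genes, 348 higher and 352 lower in KO cells. Bcl3 (-1.97 ± 0.079) fell and Ikzf2 (1.42 ± 0.18) rose, while Foxp3 (628 ± 23.5 against 627 ± 22.4 CPM) did not pass (adjusted p = 1). Il9r (4.61 ± 0.56), Ccl5 (4.21 ± 0.40) and Nkg7 (3.89 ± 0.49) rose, and Sh3d19 (-7.26 ± 1.21), Cd8b1 (-5.30 ± 0.45), Prkce (-5.05 ± 0.75), Ccl20 (-4.83 ± 0.45) and Gbp10 (-3.87 ± 0.37) fell. Entpd1 (0.68 ± 0.12) rose and Izumo1r (-0.67 ± 0.074) and Gpr83 (-1.95 ± 0.25) fell. 4 of 20 Treg signature genes fell, 2 rose and 14 did not pass (10 over the list alone, camera adjusted p = 0.67). With Cxcr3 (1.08 ± 0.20), 5 of 17 Th1 genes rose, 1 fell and 11 did not pass (6 over the list alone, camera adjusted p = 1.1e-06 for higher, 0.21 with an estimated correlation). Ccr9 (-2.90 ± 0.26), Gpr15 (-2.17 ± 0.22) and Gpr183 (-1.50 ± 0.17) fell. 4 of 14 gut homing and residency genes fell, 2 rose and 8 did not pass (7 over the list alone, camera adjusted p = 0.0024 for lower, 0.15 with an estimated correlation). With Sqle (1.03 ± 0.12), 6 of 18 cholesterol synthesis genes rose, 0 fell and 12 did not pass (9 over the list alone, camera adjusted p = 5.3e-07 for higher, 0.15 with an estimated correlation). Isg15 (-1.04 ± 0.18) fell. Nfkbid (-0.84 ± 0.11), Tcf7 (-0.85 ± 0.12) and Mcm7 (-0.66 ± 0.12) fell and Tnf (1.13 ± 0.20), Cd44 (0.64 ± 0.083) and Bcl2l1 (1.43 ± 0.088) rose. By the Bcl3 locus, Igsf23 (2.96 ± 0.14) rose, Ccdc61 (-2.79 ± 0.29) fell and Cblc (4.12 ± 1.56 against 0 CPM) was read in KO cells alone, and 10 of 85 neighbourhood genes fell, 7 rose and 68 did not pass (25 over the list alone, camera adjusted p = 0.94). Markers of other cells summed to 10.3 ± 5.71 against 28.37 ± 5.49 CPM (CD8 and NK cells). The total was 446 without WT1, 1242 with DESeq2 and 371 fitting only the 2 groups compared.

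The tTregs of mLN differed in 594 genes, 369 higher and 225 lower in KO cells. Bcl3 reads (-0.53 ± 0.077, not corrected for the shorter KO transcript) and Il2ra (-0.39 ± 0.071) fell. Apol11b (7.45 ± 1.24), Wnt10a (5.00 ± 0.37), Gzmb (3.91 ± 0.52), Cx3cl1 (3.85 ± 0.46) and Ccl5 (3.62 ± 0.37) rose, and Sh3d19 (-6.34 ± 1.09), Prkce (-3.93 ± 0.68), Cd8b1 (-3.43 ± 0.40) and Tspoap1 (-3.03 ± 0.53) fell. With Cd44 (0.82 ± 0.084), Cxcr3 (1.82 ± 0.20) and Batf (0.78 ± 0.11), 10 of 23 effector Treg genes rose, 1 fell and 12 did not pass (14 over the list alone, camera adjusted p = 9.4e-15 for higher, 0.053 with an estimated correlation). With Tbx21 (1.63 ± 0.23), which encodes T-bet, 8 of 17 Th1 genes rose, 0 fell and 9 did not pass (9 over the list alone, camera adjusted p = 9.6e-18 for higher, 0.053 with an estimated correlation). Gapdh (0.44 ± 0.081) and Aldoa (0.39 ± 0.073) rose. 4 of 17 glycolysis genes rose, 0 fell and 13 did not pass (10 over the list alone, camera adjusted p = 1.9e-07 for higher, 0.11 with an estimated correlation). Gbp2 (0.95 ± 0.11) and Irf1 (0.54 ± 0.089) rose, and the atypical IkB genes Nfkbid (-1.28 ± 0.11) and Nfkbiz (-1.35 ± 0.22) fell. Bcl2l1 (1.35 ± 0.088) rose and Bbc3 (-1.18 ± 0.19) fell. With Cd74 (1.44 ± 0.13), 2 of 11 myeloid genes rose, 0 fell and 9 did not pass (3 over the list alone, camera adjusted p = 2.1e-05 for higher, 0.14 with an estimated correlation). By the Bcl3 locus, Igsf23 (2.21 ± 0.14) rose and Slc1a5 (-1.27 ± 0.14) fell. 15 of 85 neighbourhood genes fell, 3 rose and 67 did not pass (30 over the list alone, camera adjusted p = 0.021 for lower, 0.11 with an estimated correlation). Sums of such markers were 21.73 ± 1.55 against 44.53 ± 2.12 CPM (CD8 and NK cells) and 343.3 ± 6.33 against 178 ± 18 (myeloid cells). The total was 281 without WT2, 355 without WT3, 275 without KO1, 300 without KO3, 1215 with DESeq2 and 1058 fitting only the 2 groups compared.

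In spleen, KO pTregs differed in 893 genes, 510 higher and 383 lower. Gzmb (4.92 ± 0.27), Nox1 (4.04 ± 0.46), Il10 (3.56 ± 0.64) and Ctla4 (0.60 ± 0.10) rose. Sh3d19 (0 against 8.52 ± 1.18 CPM) and Bcam (0 against 7.79 ± 1.42 CPM) were read in WT cells alone. With Cxcr3 (1.77 ± 0.12), Fgl2 (2.07 ± 0.15) and Tnfrsf1b (0.87 ± 0.069), 11 of 23 effector Treg genes rose, 0 fell and 12 did not pass (17 over the list alone, camera adjusted p = 9.4e-27 for higher). With Ccl5 (3.53 ± 0.20) and Id2 (1.56 ± 0.14), 8 of 16 Th1 genes rose, 1 fell and 7 did not pass (11 over the list alone, camera adjusted p = 1.3e-21 for higher). Tcf7 (-0.71 ± 0.081), Id3 (-1.45 ± 0.18), Foxp1 (-0.57 ± 0.083) and Bcl2 (-0.76 ± 0.11) fell. 8 of 14 naive and central memory genes fell, 0 rose and 6 did not pass (10 over the list alone, camera adjusted p = 3.7e-14 for lower, 0.093 with an estimated correlation). Tnf (1.60 ± 0.25), Icam1 (0.77 ± 0.15), Icos (0.71 ± 0.12) and Batf (0.70 ± 0.11) rose, and Gpr83 (-2.68 ± 0.28), Izumo1r (-0.92 ± 0.11), Gpr183 (-1.28 ± 0.15) and Fas (-0.63 ± 0.089) fell. Bcl2l1 (1.62 ± 0.12) and Igsf23 (2.09 ± 0.23) rose. Of other cells, markers summed to 10.37 ± 3.51 against 29.2 ± 4.01 CPM (CD8 and NK cells). The total was 580 without WT1, 578 without WT2, 1610 with DESeq2 and 281 fitting only the 2 groups compared.

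In spleen, KO tTregs differed in 198 genes, 141 higher and 57 lower. Sytl4 (5.23 ± 0.36), Wnt10a (4.02 ± 0.38), Nox1 (3.89 ± 0.47) and Apol10b (3.36 ± 0.27) rose most, and Cd8b1 (-4.84 ± 0.76), Bcam (-3.23 ± 0.29), Gbp10 (-2.32 ± 0.22) and Sema4a (-2.30 ± 0.30) fell most. With Cxcr3 (1.44 ± 0.12), Gzmb (2.40 ± 0.24), Tnfrsf1b (0.64 ± 0.068) and Cd44 (1.06 ± 0.12), 7 of 23 effector Treg genes rose, 0 fell and 16 did not pass (10 over the list alone, camera adjusted p = 7.4e-15 for higher). With Ccl5 (1.74 ± 0.18), 5 of 16 Th1 genes rose, 0 fell and 11 did not pass (7 over the list alone, camera adjusted p = 3.8e-17 for higher). 3 of 17 glycolysis genes rose, 0 fell and 14 did not pass (5 over the list alone, camera adjusted p = 5.6e-07 for higher, 0.055 with an estimated correlation). Entpd1 (1.12 ± 0.16), Gbp2 (0.71 ± 0.11) and Bcl2l1 (1.33 ± 0.11) rose and Gpr183 (-2.11 ± 0.16) fell. By the Bcl3 locus, Igsf23 (2.50 ± 0.23) rose, Slc1a5 (-1.46 ± 0.17) fell and Cblc (5.48 ± 2.16 against 0.00863 ± 0.0149 CPM) was near absent from WT cells. Summed markers of other cells stood at 15 ± 1.97 against 39.23 ± 2.36 CPM (CD8 and NK cells) and 270 ± 32.5 against 177.2 ± 23.2 (myeloid cells). The total was 124 without WT1, 90 without WT2, 95 without KO1, 105 without KO2, 108 without KO3, 459 with DESeq2 and 540 fitting only the 2 groups compared, and 179 with replicate as a block.

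The KO effect differed between mLN pTregs and tTregs in 115 genes, 40 more positive in pTregs and 75 more negative. Bcl3 changed by -1.97 ± 0.079 against -0.53 ± 0.077 in tTregs (difference -1.44 ± 0.11, adjusted p = 0.000137). The total was 40 without pTreg WT1, 30 without tTreg WT2, 57 without pTreg WT2, 27 without tTreg WT3, 30 without tTreg KO1, 29 without tTreg KO3, 180 with no count filter and 561 with DESeq2. In spleen 49 genes differed, 25 more positive and 24 more negative in pTregs. Gzmb rose in both, by 4.92 ± 0.27 against 2.40 ± 0.24 (2.53 ± 0.34, adjusted p = 0.00833). That total was 12 without tTreg WT1, 25 without pTreg WT2, 12 without tTreg WT2, 111 without pTreg WT3, 29 without tTreg WT3, 11 without tTreg KO1, 17 without tTreg KO2, 11 without tTreg KO3, 77 with no count filter, 294 with DESeq2 and 12 with replicate as a block.

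In SI pTregs, edgeR called 2 genes, both higher in KO cells, and 426 had an unadjusted p under 0.05. Cd83, a marker of activated lymphocytes, stood at 1474 ± 308 against 352 ± 27.8 CPM (adjusted p = 0.0226) and Tnfrsf8, which encodes CD30, at 105 ± 22.8 against 19.4 ± 2.29 CPM (adjusted p = 0.0301). Tnfrsf8 lost its call without any 1 of the 6 libraries and Cd83 without any but KO2. Bcl2l1 had 223 ± 25.2 against 71.8 ± 14.9 CPM without passing (adjusted p = 0.0636). The total was 1 without WT1, 0 without WT2, 0 without WT3, 0 without KO1, 1 without KO2, 0 without KO3, 64 with DESeq2, 5 fitting only the 2 groups compared, 0 with replicate as a block, 0 with sex as a term, 4 without immunoglobulin genes and Jchain and 7 without tTreg KO libraries 2 and 3. In SI tTregs 1 gene was called and 1210 had an unadjusted p under 0.05. It was Mmp25, with no counts in KO cells and 3.172 ± 0.5029 CPM in WT cells, chosen here after its values were seen. 0 of 10 Th2 genes rose, 0 fell and 10 did not pass (4 over the list alone, camera adjusted p = 8.5e-06 for lower). That total was 2 without WT2, 509 without KO1, 12 without KO2, 5 without KO3, 184 with DESeq2, 2 with replicate as a block and 14 without tTreg KO libraries 2 and 3. Mmp25 was also the 1 gene whose KO effect differed between pTregs and tTregs, where 480 had an unadjusted p under 0.05. This total was 140 without tTreg KO1 and 61 with DESeq2, and 0 with replicate as a block. Among SI libraries Foxp3 stood at 55.54 CPM in tTreg KO2 and 292.23 in tTreg KO3, against 515.24 to 782.67 in the others. Igha, an antibody heavy chain gene, ran from 6.93 CPM in tTreg KO2 to 95908 in pTreg WT2. Plasma cell markers summed to 74800 ± 48300 CPM in WT and 30550 ± 37300 in KO pTregs.

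**Figure D4:**
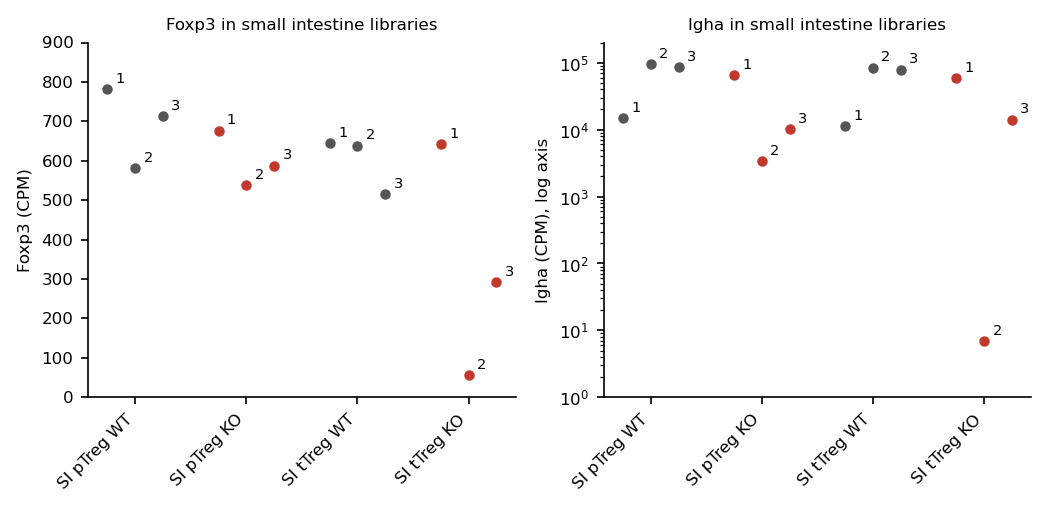
Foxp3 (linear axis) and Igha (log axis) CPM in each of the 12 SI libraries. Points are libraries.

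Between SI and mLN, WT pTregs differed in 2058 genes, 1210 higher and 848 lower in SI. Il10 (3.90 ± 0.39) and Ctla4 (1.33 ± 0.16) rose and Il2ra (-1.57 ± 0.11) fell. Jchain (14.50 ± 1.32) and Igha (15.51 ± 1.37), genes of antibody-secreting cells, rose most. 7 of 8 plasma cell genes rose, 0 fell and 1 did not pass (8 over the list alone, camera adjusted p = 2.2e-12 for higher, 0.05 with an estimated correlation). With Cd68 (4.89 ± 0.45) and H2-Aa (6.73 ± 0.62), 13 of 14 myeloid genes rose, 0 fell and 1 did not pass (14 over the list alone, camera adjusted p = 2.8e-23 for higher). Dusp1 (5.41 ± 0.12), Junb (4.27 ± 0.18), Fos (6.02 ± 0.27) and Jun (3.96 ± 0.20) rose. 14 of 21 immediate early and heat shock genes rose, 2 fell and 5 did not pass (18 over the list alone, camera adjusted p = 4.2e-41 for higher). With Nkg7 (6.26 ± 0.34) and Id2 (2.23 ± 0.16), 10 of 17 Th1 genes rose, 0 fell and 7 did not pass (11 over the list alone, camera adjusted p = 1.8e-14 for higher). With Rgs1 (2.84 ± 0.12), Cd69 (2.92 ± 0.13) and Ccr9 (2.51 ± 0.18), 4 of 14 gut homing and residency genes rose, 1 fell and 9 did not pass (8 over the list alone, camera adjusted p = 4.6e-06 for higher). With Sqle (2.11 ± 0.21), 16 of 18 cholesterol synthesis genes rose, 0 fell and 2 did not pass (16 over the list alone, camera adjusted p = 1.4e-17 for higher, 0.051 with an estimated correlation). Tnfaip3 (5.02 ± 0.22) and Nfkbia (2.49 ± 0.11), which restrain NF-kB, rose, as did Areg (6.48 ± 0.41), Fgl2 (1.59 ± 0.11) and Gzmb (3.99 ± 0.41), and Tcf7 (-2.94 ± 0.27), Lef1 (-1.20 ± 0.13) and mt-Cytb (-0.51 ± 0.068) fell. Sums of other markers were 32950 ± 20000 against 2067 ± 56.9 CPM (B cells), 43.8 ± 18.9 against 16.6 ± 5.88 (epithelial cells), 3336 ± 1700 against 368.5 ± 30.3 (myeloid cells), 74800 ± 48300 against 340 ± 15.4 (plasma cells) and 36.77 ± 13.5 against 72 ± 7.71 (stromal and endothelial cells). The total was 1215 without mLN pTreg WT1, 1218 without mLN pTreg WT2, 1180 without mLN pTreg WT3, 3129 with DESeq2 and 1149 with replicate as a block and only the 2 groups.

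For WT tTregs the tissues differed in 4010 genes, 2318 higher and 1692 lower in SI. Il10 (8.64 ± 0.50), Ctla4 (2.90 ± 0.17) and Bcl3 (0.53 ± 0.13) rose, and Il2ra (-1.75 ± 0.12) and Nrp1 (-1.98 ± 0.20) fell. Jchain (16.05 ± 1.41) and Igha (16.95 ± 1.44) were among the largest rises. With Areg (9.16 ± 0.47), Icos (2.35 ± 0.11) and Ccr2 (5.59 ± 0.26), 22 of 23 effector Treg genes rose, 0 fell and 1 did not pass (22 over the list alone, camera adjusted p = 1.9e-48 for higher). With Gzmb (10.17 ± 0.54), 15 of 17 Th1 genes rose, 1 fell and 1 did not pass (17 over the list alone, camera adjusted p = 1.7e-29 for higher). With Gata3 (2.56 ± 0.17), 9 of 10 Th2 genes rose, 0 fell and 1 did not pass (10 over the list alone, camera adjusted p = 7.1e-16 for higher). With Ccr9 (4.71 ± 0.20) and Cd69 (2.49 ± 0.13), 13 of 14 gut homing and residency genes rose, 0 fell and 1 did not pass (13 over the list alone, camera adjusted p = 4.1e-30 for higher). Dusp1 (5.91 ± 0.12), Fos (7.10 ± 0.28), Tnfaip3 (5.37 ± 0.22), Nfkbiz (4.06 ± 0.23) and Rrm2 (1.83 ± 0.22) rose, and Tcf7 (-2.31 ± 0.26) and Ly6c1 (-4.09 ± 0.38) fell. Of other cell types, 8 of 8 plasma cell genes rose, 0 fell and 0 did not pass (8 over the list alone, camera adjusted p = 1.3e-08 for higher, 0.1 with an estimated correlation), 5 of 8 CD8 and NK genes rose, 1 fell and 2 did not pass (6 over the list alone, camera adjusted p = 0.19), 5 of 12 B cell genes rose, 1 fell and 6 did not pass (8 over the list alone, camera adjusted p = 0.047 for higher, 0.36 with an estimated correlation) and 2 of 5 epithelial genes rose, 1 fell and 2 did not pass (3 over the list alone, camera adjusted p = 0.11). Their sums stood at 31290 ± 22300 against 1113 ± 59.9 CPM (B cells), 679.1 ± 76.9 against 44.53 ± 2.12 (CD8 and NK cells), 113.1 ± 20.5 against 30.27 ± 1.82 (epithelial cells), 26.7 ± 8.31 against 4 ± 0.265 (erythroid cells), 2395 ± 1170 against 178 ± 18 (myeloid cells), 67610 ± 45800 against 180.1 ± 19.5 (plasma cells) and 47.93 ± 7.25 against 191.4 ± 19 (stromal and endothelial cells). The total was 2656 without mLN tTreg WT2 and 2646 with replicate as a block and only the 2 groups.

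Across the 8 KO comparisons of mLN and spleen, 13712 genes were tested in all, and 10 changed the same way in every one. Bcl2l1, Cblc, Cd86, Fbxo17, Igsf23 and Ildr1 were higher in KO cells, and Alkbh6, Bcam, Ccdc61 and Rflnb were lower. Of the 10, 6 lie on chromosome 7, among them Bcam, Cblc, Ccdc61 and Igsf23 within 1 Mb of Bcl3, and Cd86 and Ildr1 lie close together on chromosome 16. At least 7 comparisons shared 27 genes and at least 5 shared 108. KO calls in mLN and spleen Tregs shared 139 genes in the same direction and 2 in opposite ones, against 4.8 in the same if independent. For Th cells these were 91 and 10 against 2.6, for pTregs 255 and 5 against 22, and for tTregs 135 and 0 against 4.6. In both organs 40 genes changed the same way in KO and OE Tregs, so Treg/Th overlaps may not all be effects of Bcl3 loss. Within mLN, Tregs and Th cells shared 165 in the same direction (independent 6.3), and pTregs and tTregs 198 (independent 14.4). Tregs of mLN and the tTregs of the other experiment, which share no library, had 161 in common and 0 opposite (independent 10.4).

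**Figure D5:**
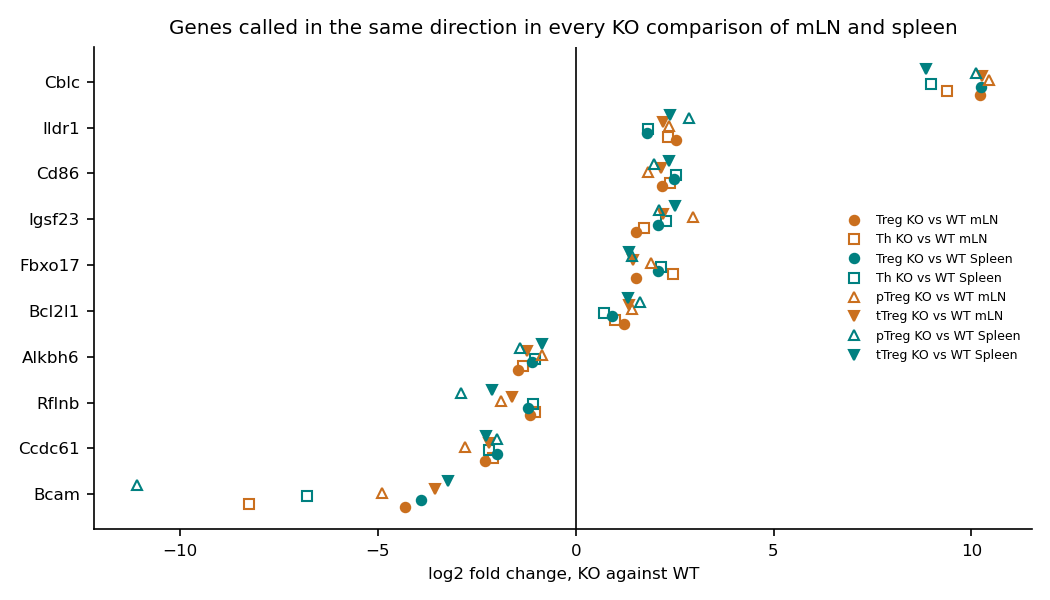
Log2 folds of KO over WT cells for the 10 genes called the same way in all 8 KO comparisons of mLN and spleen. Folds of Cblc and Bcam rest on groups with counts near 0.

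KO and OE Tregs were each compared with the same WT libraries. In mLN, 63 genes changed the same way and 39 in opposite ways, against 4.2 and 4.3 if independent. Spleen gave 95 and 25, against 7.2 and 6.9. Shared WT libraries alone make the folds vary together, by a mean covariance of 0.302 (correlation 0.497) in mLN and 0.312 (0.489) in spleen over 20 simulations. In the data it was 0.334 (0.321) and 0.56 (0.46). Th cells shared 179 genes in the same direction and 0 in opposite ones in mLN (independent 6.4 and 4), and 56 and 9 in spleen (independent 1.5 and 2.3). Their covariances were 0.862 and 0.521 (correlations 0.552 and 0.407), against simulated ones of 0.29 and 0.286 (0.511 and 0.479). In mLN Tregs, Ctse, Cxcr2 and Lad1 changed the same way in both.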

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

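Of the tests in this part, those of shared WT libraries, of another WT background, of loss and gain of Bcl3, of Foxp3+ cells in the Th gate and of Bcl3 in Th cells were chosen after the result was seen.

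The difference between KO effects in 2 cell types passed for 59 genes in mLN (Tregs against Th cells), 39 in spleen, 115 in mLN (pTregs against tTregs), 49 in spleen and 1 in SI. In mLN, Tregs less Th cells, the difference was -1.578 for Bcl3, -6.046 for Ccl4 and -1.367 for Ctla4. In spleen it was -1.668 for Bcl3, -1.032 for Foxp3 and 1.305 for Pglyrp1. Foxp3 (adjusted p = 0.0212) was lost without Treg WT5, Treg WT6, Th WT7 or Th KO2, at most with adjusted p = 0.0669. Pglyrp1 (adjusted p = 0.023) was lost without Treg WT6, Treg KO3, Th WT6, Th WT7 or Th KO2, at most with adjusted p = 0.0809. For pTregs less tTregs in mLN it was -1.437 for Bcl3 and 1.394 for Ikzf2 (adjusted p = 0.0264), the latter lost without pTreg WT1 or WT2 or tTreg WT2, KO1, KO2 or KO3, at most with adjusted p = 0.0727. Cx3cl1 had a fitted difference of 5.811 that rested on WT pTregs near 0 counts, and 8 of its 12 leave-outs ended the call. In spleen Gzmb differed by 2.527, and Bcam, with no counts in KO pTregs, had a fitted -7.855 that is no bound. Arhgap20, with a fitted -6.87 (adjusted p = 0.0475), was lost in 11 of its 12 leave-outs. The replicate number as a block within genotype also ended the calls of Foxp3 (-1.035, adjusted p = 0.21), Pglyrp1 (1.292, 0.336), Cx3cl1 (5.642, 0.0791) and Arhgap20 (-6.621, 0.195), with differences little moved, and those of Bcl3, Ccl4 and Ctla4 for mLN Tregs less Th cells.

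For these differences, splits that mixed the libraries were counted among 40 drawn, the real one included. In mLN, Tregs against Th cells, 2 of 40 gave as many genes (real 59, highest other 361). That split held a difference of its own, whose cause was not tested. That split set WT5, WT7 and KO2 against WT6, KO1 and KO3, which also differed in mitochondrial share of counts, in Tregs (1.267 to 1.413 against 2.256 to 2.54 percent) and, the other way round, in Th cells (2.213 to 2.612 against 1.66 to 1.865). With Th sides exchanged it gave 0. With that share as a term the real difference gave 66 genes, 55 of them in common. In spleen 1 of 40 gave as many genes (real 39, highest other 32), with 27 genes without Treg WT6 and 7 with replicate as a block. The split with 32 left KO and WT Th libraries unmixed. For pTregs against tTregs in mLN, 1 of 40 gave as many genes (real 115, highest other 42), though leaving out 1 library gave as few as 27 (without tTreg WT3). In spleen 2 of 40 did (real 49, highest other 57), and the split with 57 left KO and WT pTregs unmixed. In SI 10 of 40 did (real 1, highest other 21).

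The comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05, and only the real count and the highest other are given. They were 494 and 1 for Treg KO, 254 and 0 for Treg OE, 364 and 3 for Th KO, 417 and 1 for Th OE and 2506 and 1 for Treg against Th cells in mLN. In spleen they were 282 and 0, 741 and 1, 235 and 5, 236 and 0, and 2589 and 1 in the same order. For pTreg KO, tTreg KO and pTregs against tTregs they were 700 and 5, 594 and 0, and 4202 and 0 in mLN, and 893 and 12, 198 and 0, and 3119 and 0 in spleen. In SI they were 2 and 0, 1 and 5, and 49 and 0, with 2 splits as large for tTreg KO. SI against mLN gave 2058 and 0 for pTregs and 4010 and 0 for tTregs.

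The first pattern is 63 genes in mLN and 95 in spleen that changed the same way in KO and OE Tregs. Chance values of WT libraries would not recur in the other organ, which has others. Yet signed median folds there were 91.8 percent of those here for mLN genes and 74 for spleen genes, which argues against them. If loss and gain of Bcl3 both moved these genes, KO tTregs of the other experiment, with other WT libraries, should show them. Yet their signed medians there were 0.093 in mLN and 0.074 in spleen (7 and 5.5 percent of 1.329 and 1.344 here). Such low values would arise if Treg/Th WT mice differed from KO and OE mice in more than Bcl3 (strain, housing, litter). Chance would give them too if libraries of 1 number came from 1 mouse. But 20 simulations of unchanged groups gave at most 0 such genes, which argues against chance for these sets. In Ctse and Gm8822 (89.23 to 136.9 CPM, at most 6.7 elsewhere) those WT libraries stood apart from other WT ones too.

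The second pattern is the rise of Treg genes in Th cells of OE mice. Of genes over 8-fold higher in WT Tregs, 88 of 139 rose in mLN and 60 of 106 in spleen, and 0 fell. Of genes 8-fold lower there 0 of 78 and 0 of 117 rose, with median folds of -0.367 and -0.316. Both sets were picked by the same WT Th libraries, which alone favours these signs, so the signs are no test of admixed Tregs. Foxp3+ cells inside the Foxp3- gate remain open, since these genes would need a median of 21 percent of OE Treg RNA in mLN and 20.8 in spleen, whereas Foxp3 would need 7.9 and 7.3, Lrrc32 6.2 and 7.3, Il2ra 9.3 and 7.3, Ctla4 18.4 and 17.7 and Ikzf2 19 and 16.7. Bcl3 overexpression in Th cells stays open too, since Bcl3 changed there by 0.253 and 0.301, without passing (upper limits 0.648 and 0.637).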

How the results depend on the processing

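Of the tests in this part, the terms for sex and mitochondrial share, SI without 2 tTreg KO libraries, SI without immunoglobulin genes, and the Treg/Th fits without genes changed the same way in KO and OE cells or without Treg genes were chosen after the result was seen. For 1120 named gene results, 12326 refits kept direction and side of the threshold, 1268 lost the call and 7 gained it. In 7 refits Foxp3, close to 0, changed sign without passing: KO pTregs of mLN at -0.007 with no filter and from -0.03 to 0.029 without 1 library, and WT pTregs against tTregs of mLN from -0.045 to 0.013 without 1 library. Counts under RLE size factors, and with mitochondrial share as a term, stayed within 1.5 times. Without each library in turn, counts of genes ran over 158 to 297 (Th KO spleen), 255 to 342 (Th KO mLN), 182 to 220 (Th OE spleen), 255 to 459 (Th OE mLN), 161 to 280 (Treg KO spleen), 273 to 620 (Treg KO mLN), 398 to 531 (Treg OE spleen), 153 to 183 (Treg OE mLN), 2022 to 2373 (Treg vs Th spleen), 1813 to 2240 (Treg vs Th mLN), 0 to 1 (pTreg KO SI), 578 to 860 (pTreg KO spleen), 446 to 666 (pTreg KO mLN), 1180 to 1870 (pTreg SI vs mLN), 14 to 23 (pTreg vs tTreg SI), 1744 to 3165 (pTreg vs tTreg spleen), 3204 to 3822 (pTreg vs tTreg mLN), 1 to 509 (tTreg KO SI), 90 to 165 (tTreg KO spleen), 275 to 471 (tTreg KO mLN), 2656 to 3985 (tTreg SI vs mLN), 27 to 56 (Treg against Th spleen), 29 to 68 (Treg against Th mLN), 1 to 140 (pTreg against tTreg SI), 11 to 111 (pTreg against tTreg spleen) and 27 to 140 (pTreg against tTreg mLN). A group left with 2 libraries used the spread pooled over the fit. DESeq2 gave 877 (Treg KO mLN), 488 (Treg OE mLN), 709 (Th KO mLN), 727 (Th OE mLN), 196 (Treg against Th mLN), 556 (Treg KO spleen), 1118 (Treg OE spleen), 472 (Th KO spleen), 411 (Th OE spleen), 128 (Treg against Th spleen), 1242 (pTreg KO mLN), 1215 (tTreg KO mLN), 561 (pTreg against tTreg mLN), 1610 (pTreg KO spleen), 459 (tTreg KO spleen), 294 (pTreg against tTreg spleen), 64 (pTreg KO SI), 184 (tTreg KO SI), 226 (pTreg vs tTreg SI), 61 (pTreg against tTreg SI) and 3129 (pTreg SI vs mLN). With only the 2 groups compared there were 393 (Treg OE mLN), 211 (Th KO mLN), 121 (Th OE mLN), 136 (Th KO spleen), 134 (Th OE spleen), 371 (pTreg KO mLN), 1058 (tTreg KO mLN), 281 (pTreg KO spleen), 540 (tTreg KO spleen), 5 (pTreg KO SI) and 160 (pTreg vs tTreg SI). With no filter there were 180 and 77 (pTreg against tTreg, mLN and spleen). The replicate number as a block gave 0 (pTreg KO SI) and 2 (tTreg KO SI), within genotype 2 (Treg against Th mLN), 7 (Treg against Th spleen) and 12 (pTreg against tTreg spleen), and with only the 2 groups 1374 (Treg vs Th spleen), 117 (pTreg vs tTreg SI), 1149 (pTreg SI vs mLN) and 2646 (tTreg SI vs mLN). Of the 20 pairings behind these blocks 3 passed the check (correlations -0.247 to 0.346). Over all 79 of 120 samples were closest to their own number, more than random matching among 3 libraries would give. So pairing by number is not excluded, and if numbers mark animals, the unblocked totals treat paired libraries as independent. Sex as a term gave 262 (Treg KO mLN), 227 (Th KO mLN), 125 (Treg KO spleen), 137 (Th KO spleen) and 0 (pTreg KO SI). The SI fit without tTreg KO libraries 2 and 3 gave 7 (pTreg KO SI), 14 (tTreg KO SI) and 172 (pTreg vs tTreg SI), and without immunoglobulin genes 4 (pTreg KO SI). Without genes changed the same way in KO and OE cells there were 157 (Treg OE mLN), 143 (Th KO mLN), 154 (Th OE mLN), 143 (Treg KO spleen) and 150 (Th KO spleen), and without genes 8-fold higher in WT Tregs 247 (Th OE mLN) and 125 (Th OE spleen). Camera called 210 of 525 list tests, 72 with an estimated correlation, and fry 205, with 165 in common. At an adjusted p under 0.1, KO overlaps in the same direction rose to 145 (Th mLN and spleen), 299 (pTreg and tTreg mLN), 396 (pTreg mLN and spleen) and 252 (Treg and tTreg mLN), and opposite KO and OE calls in mLN Tregs to 59. Leaving out libraries or genes lowers the number tested or the degrees of freedom by construction, and for the other changes the cause was not tested.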

Other observations

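The follow-up in the other experiment, the genes named here and the reading of sex were tests chosen after the result was seen. In Tregs, 39 genes of mLN and 25 of spleen changed in opposite ways in KO and OE cells, and 13 did so in both tissues. Of the 13, Cd86, Igsf23, Bcl2l1, Ehd3, Ildr1, Sms, Fhit, Ppic and Gpd2 were higher in KO and lower in OE cells, and Satb1, Rflnb, Prag1 and Gtf2i the reverse. Bcl2l1, which protects cells from apoptosis, stood at 1.21 in KO and -1.85 in OE Tregs of mLN, and 0.92 and -2.13 in spleen. Cd86 stood at 2.17 and -2.33, and 2.48 and -1.45. In tTregs of the other experiment, which shares no library with this one, 29 of the 39 and 16 of the 25 were called in the direction of KO Tregs and 0 in the other. Their signed median fold there was 1.294 in mLN and 1.03 in spleen. In pTregs 25 of 39 and 17 of 25 were called that way, with 1 and 0 in the other. The labels do not say whether the KO mice of the 2 experiments were the same animals.

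Reads of Xist and of Y-linked genes placed number 1 of each pTreg and tTreg group as male and numbers 2 and 3 as female. In the Treg/Th experiment WT and OE libraries were male, as was KO1, and KO2 and KO3 were female. Gt(ROSA)26Sor ran from 0 to 0.53 CPM in OE libraries, and Cap1 from 605.4 to 776.9, against at most 259.6 elsewhere.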
